A study of Mus musculus with 6 samples.

How the data were processed

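Polyadenylated RNA was sequenced from primary cortical thymic epithelial cells (cTECs) taken from the thymus of mice aged 8 to 10 weeks. There were 6 libraries, 3 from mice lacking Psmb11 (KO, replicates A to C) and 3 from wild-type mice (WT, replicates A to C). The series design also names medullary epithelial cells and thymocyte subsets, which were not analysed here. The labels do not state whether the 3 replicates of a genotype came from separate mice, so every p-value measures only the spread between these samples.

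Per the submitters' processing notes, reads were prepared with bcl2fastq 2.17, aligned with STAR 2.5.1b and quantified with RSEM 1.2.28. The notes give the genome build as GRCh38, a human build, while the gene identifiers in the files are mouse Ensembl identifiers. The build used for alignment is therefore uncertain, and symbols and positions were looked up in the mouse annotation GENCODE M21 (build GRCm38). Of 50600 gene identifiers, 50376 (99.56%) matched by identifier, 45737 of them with the same version, and 136 shared a symbol with another identifier.

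The deposited read counts are raw counts per gene with a column for each strand setting, and the column for the opposite strand was used because it held nearly all gene counts. The authors also deposited RSEM expected counts per gene, which are estimated reads and not all whole numbers. The deposited TPM values are transcript abundances by RSEM, scaled for length and to a common total per library. Expected counts and TPM were used in alternatives only.

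The gene counts per library were 36713388, 36706526 and 34265035 in KO replicates A, B and C and 34660349, 36161101 and 39224292 in WT replicates A, B and C. TMM factors lay between 0.9937 and 1.0118, and the common biological coefficient of variation was 0.0538. Between libraries of one genotype the spread averaged 5.18 to 9.07 times the variance of counting alone over 12241 genes; genes with few counts are limited by counting as well.

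Genes passing filterByExpr were compared between KO and WT with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with TMM normalization and no block. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Levels are CPM, counts scaled to a common library size, given as mean ± SD over 3 libraries. Log2 fold changes are KO over WT. Their SE was derived from the F statistic of the test, which is approximate and least reliable for large changes. Gene lists were fixed before the data were examined, as were the comparisons, the tests and most alternatives, and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 27 lists. Each list was tested again with a correlation estimated from its own members. That form of camera uses the few residual degrees of freedom of the libraries, which raises p by itself. Lists with fewer than 3 measured members were not tested, which left out the erythroid list, and the sex-specific genes served only to check the libraries.

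Named genes followed a rule fixed beforehand. The rule took Psmb11, then the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 CPM in the higher group, no overlap between groups and an established symbol. It then took up to 4 called members of each list by increasing p, or up to 2 members with the highest CPM where none was called, and up to 4 called genes within 10 Mb of Psmb11. Other members of a list are given as examples of that list.

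The number of genes at 1 CPM or more per library was compared with an exact two-sided permutation test. The share of called genes near Psmb11 was compared with Fisher's exact test, two-sided. The method was tested on simulated data with 200 changed genes. It found 44% of changes of 1.25-fold, 66% of 1.5-fold, 80% of 2-fold and 98% of 4-fold, with 0 in the wrong direction. False calls made up 11.66% of calls in that single draw, above the 5% aimed at, and 4.63% of unchanged genes had an unadjusted p below 0.05. Far fewer genes were changed there than were called in the data (3989 of 16938). The adjusted p depends on the share of changed genes, so the shares found and falsely called may not carry over.

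Alternatives were RLE and upper quartile normalization, DESeq2 1.42.0, no low count filter, a mean of at least 5 CPM, RSEM expected counts, limma on log2(TPM + 1) and on log2(TPM + 0.1), unstranded counts, a replicate block, a thymocyte marker covariate and leaving out each library. Lists were also tested with fry, and a test against a fold change of 1.2 was added after the data were seen, as were the counts of called list members without each library and with the block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.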

Results

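The data are RNA profiles of primary cTECs, the epithelial cells of the thymic cortex that support T cell development and positive selection. Psmb11 encodes β5t, a catalytic proteasome subunit made in these cells. The 3 KO libraries held 34265035 to 36713388 gene counts and the 3 WT libraries 34660349 to 39224292. The 10 most abundant genes took 4.20% to 4.59% of gene counts. The comparison asks which genes differ in cTECs that lack Psmb11.

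Psmb11 itself (ENSMUSG00000072423.4, chromosome 14, 54621433 to 54629556, plus strand, GRCm38) had 67, 36 and 41 counts in KO replicates A, B and C. The WT replicates had 8293, 9297 and 10027 counts. Its level was 1.33 ± 0.429 CPM in KO and 252 ± 9.88 CPM in WT (SD, n = 3 each), a 189-fold lower level in KO. The log2 fold change was -7.56 (edgeR quasi-likelihood, adjusted p = 1.65e-11). The SE derived from the F statistic, 0.10, understates the spread of the KO libraries, whose SD was 0.429 CPM on a mean of 1.33 CPM.

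Markers of cTECs were lower in KO. Of 20 measured markers 14 fell, 2 rose and 4 were not called, with a median log2 fold change of -0.38. Prss16, a thymus-specific serine protease, had 753 ± 153 CPM in KO and 1738 ± 58.1 CPM in WT, and Ccl25, a chemokine that attracts thymocyte progenitors, had 344 ± 54.0 and 734 ± 21.2 CPM (n = 3 each). Cd83 was 2.91-fold lower, while Ly75 and Cxcl12 were 1.42-fold and 1.43-fold lower. Foxn1, the transcription factor of thymic epithelial identity, and Dll4, the Notch ligand, also fell, by 1.30-fold and 1.73-fold. The checkpoint ligand Cd274 and the transcription factor Pax9 rose, by 1.31-fold and 1.09-fold. Il7 had 181 CPM in KO and 180.4 CPM in WT and was not called. The list was called with camera (adjusted p = 1.70e-15; adjusted p = 0.104 with an estimated correlation), and 16 members passed when adjusted over the list alone. With the replicate letter as a block, 11 markers were called lower, and Prss16, Cd83 and Tbata were not called (edgeR adjusted p = 0.0608 for Prss16 and 0.0554 for Cd83). Pax9 was not called without KO replicate B or C or WT replicate A or C, nor was Foxn1 without KO replicate B or WT replicate A, nor Tbata without WT replicate A or C. In the same KO libraries the markers of medullary epithelium, tuft cells and fibroblasts were higher, with median log2 fold changes of 0.40, 0.67 and 0.47.

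**Figure D1:**
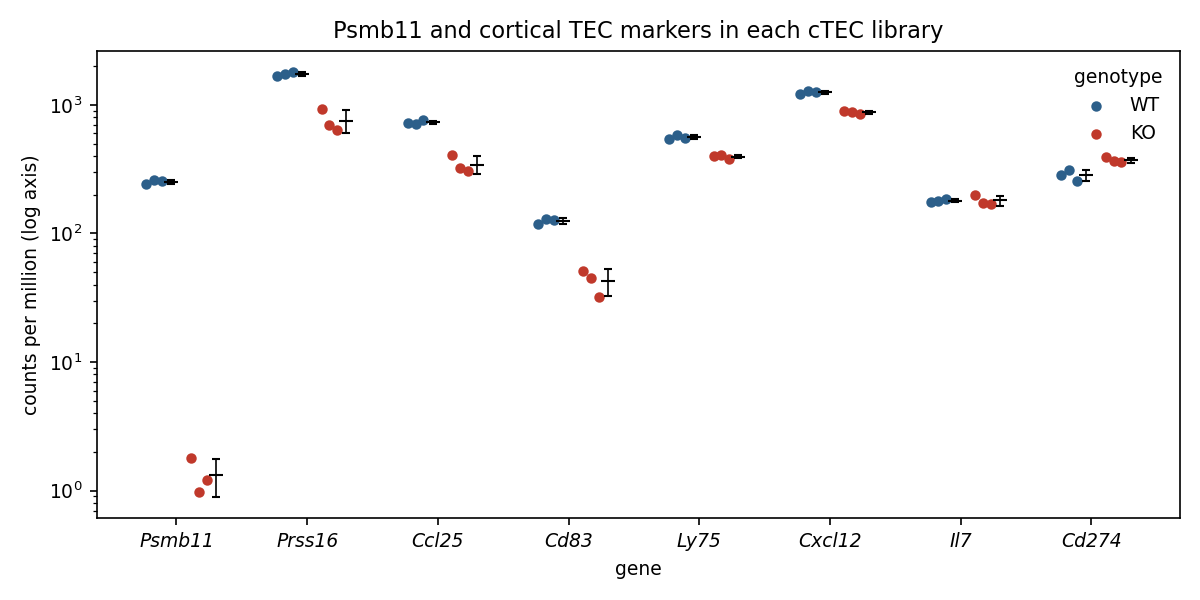
Levels of Psmb11 and 7 cortical TEC markers in CPM on a log axis, 1 point per library, with the mean and SD of each genotype in black. Psmb11 lies between 0.977 and 1.81 CPM in the KO libraries and between 241 and 259 CPM in the WT libraries.

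Across the transcriptome, 3989 of 16938 genes tested were called (23.6%; edgeR quasi-likelihood), 2113 higher and 1876 lower in KO. Most changes were small: the median fold change of called genes was 1.22, and 503 genes were at least 2-fold higher while 47 were at least 2-fold lower. Among called genes with at least 5 CPM in the higher group, the largest rises included Prss22 (3.89-fold), the urokinase receptor Plaur (3.80-fold), Prss27 (3.36-fold), the collectin Sftpd (3.34-fold), the keratin Krt4 (3.21-fold), Mal2 (3.18-fold), the coagulation factor F5 (3.13-fold), Ttn (3.10-fold), the mucin Muc20 (3.05-fold) and Pmaip1 (3.03-fold). Gabrp and Muc4 were 3.02-fold and 3.0-fold higher, and their calls were lost without KO replicate C (edgeR adjusted p = 0.0533 and 0.0515), for Gabrp also without WT replicate C (0.0692) and for Muc4 without WT replicate B (0.0523). Under the same limit, the largest falls after Psmb11 were Dync1i1 (4.31-fold), the neurofilament gene Nefm (3.29-fold), Inmt (2.79-fold), Cyp26b1, which degrades retinoic acid (2.5-fold), Acaa1b (2.47-fold), Myo16 (2.23-fold), Apba1 (2.19-fold), Hs3st6 (2.15-fold) and Nol3 (2.03-fold), with Cd83, Prss16 and Ccl25 above. The CPM values of the genotypes did not overlap for 39.3% of all genes tested, against 10% by chance. Among the called genes 3907 (97.9%) did not overlap, a share that calling by the same values favours and that is not separate support. Testing against a fold change of 1.2, chosen after the data were seen, left 954 genes, 752 higher and 202 lower. With limma on log2(TPM + 1), 2033 were called, 1221 higher and 812 lower, and without WT replicate C 1476 were higher and 1239 lower.

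**Figure D2:**
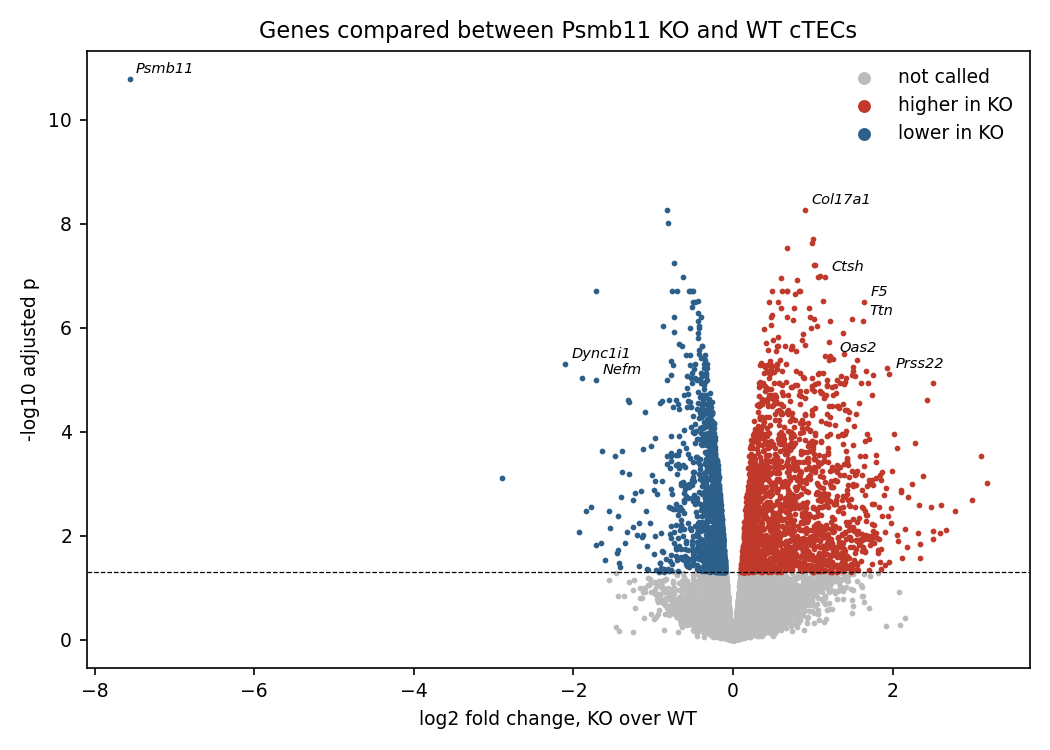
Log2 fold change (KO over WT) against -log10 of the adjusted p for 16938 genes, 1 point per gene, with the threshold of 0.05 dashed. Called genes number 2113 on the higher side and 1876 on the lower side.

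Subunits and assembly factors of the constitutive proteasome were lower in KO by small amounts: 31 of 40 fell, 0 rose and 9 were not called. Psmb4 had 127 ± 1.30 CPM in KO and 171 ± 6.83 CPM in WT (n = 3 each). Psmd1, Psmc2 and Psma6 were 1.23-fold, 1.21-fold and 1.19-fold lower. The median log2 fold change was -0.20 (camera adjusted p = 1.72e-14; adjusted p = 0.123 with an estimated correlation), and 34 members passed when adjusted over the list alone. Of 19 immunoproteasome and MHC class I genes 2 rose and 3 fell: Psmb10 and Psmb9 fell 1.36-fold and 1.21-fold, and Nlrc5, an activator of class I genes, rose 1.32-fold. That list was not called (camera adjusted p = 0.391, median log2 fold change -0.00, 7 members adjusted over the list alone). Of 16 MHC class II genes 9 fell and 2, Ctss and Lgmn, rose, Lgmn not without KO replicate B or C or WT replicate A or C. H2-Aa, H2-DMa and H2-DMb2 were 1.21-fold, 1.2-fold and 1.23-fold lower, whereas the protease Ctss was 2.03-fold higher, from 5.82 ± 0.841 CPM to 11.8 ± 0.710 CPM (n = 3 each). The class II list had a median of -0.19 (camera adjusted p = 4.93e-04; adjusted p = 0.104 with an estimated correlation), with 12 members adjusted over the list alone. Dendritic cell and macrophage markers were higher in the same libraries, with a median log2 fold change of 0.55.

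Genes induced by interferon were higher in KO: 20 of 29 rose and 1, Ifi27l2a, fell, which was not called without KO replicate B or C or WT replicate A or C. Among them Oas2, Mx1, Mx2 and Rsad2 rose 2.38-fold, 1.49-fold, 1.48-fold and 1.46-fold. Mx2 is annotated as a polymorphic pseudogene. Isg15 had 182 CPM in KO and 181 CPM in WT and was not called. The median log2 fold change was 0.21 (camera adjusted p = 2.43e-12; adjusted p = 0.104 with an estimated correlation), and 24 members passed when adjusted over the list alone. Immediate early genes, which respond quickly to stimuli and to tissue dissociation, were also higher, with 20 of 23 called. Klf6 had 579 ± 7.91 CPM in KO and 391 ± 25.2 CPM in WT (n = 3 each), and Egr2, Nr4a1 and Ier5 rose 1.79-fold, 1.65-fold and 1.30-fold. Their median was 0.36 (camera adjusted p = 1.17e-15; adjusted p = 0.172 with an estimated correlation), with 22 members adjusted over the list alone. Of 20 NF-kappaB targets 9 rose and 2 fell (1 without KO replicate B or C or WT replicate A or C, 0 without WT replicate B), with Tnf 3.99-fold, Cxcl2 2.23-fold, Ccl2 1.56-fold and Tnfaip3 1.29-fold among the rises. Tnf and Cxcl2 had low levels, 1.44 and 1.83 CPM in KO and 0.360 and 0.815 CPM in WT. The list was called (camera adjusted p = 0.00339, median 0.12; adjusted p = 0.221 with an estimated correlation; 11 members adjusted over the list alone). Of 20 p53 targets 8 rose and 2 fell (1 without KO replicate A or B or WT replicate A or C, 0 without WT replicate B), with Cdkn1a, Plk2 and Mdm2 1.71-fold, 1.42-fold and 1.19-fold higher (camera adjusted p = 0.00167, median 0.16; adjusted p = 0.221 with an estimated correlation; 11 members adjusted over the list alone). In the same KO libraries the dendritic cell and macrophage markers had a median log2 fold change of 0.55 and the fibroblast markers of 0.47.

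Cholesterol synthesis genes were lower in KO. Of 20 measured, 14 fell and 0 rose, among them Mvk 1.59-fold, the regulator Srebf2 1.27-fold and Sc5d 1.2-fold (median -0.44, camera adjusted p = 2.06e-10; adjusted p = 0.221 with an estimated correlation; 16 members adjusted over the list alone). The falls called numbered 10 without KO replicate A, KO replicate C or WT replicate A. They numbered 11 without WT replicate B, 12 without WT replicate C and 16 without KO replicate B. Cortical TEC markers fell in the same libraries, with a median log2 fold change of -0.38. Of 25 genes of the oxidative stress response 13 fell and 2 rose, Slc7a11 1.64-fold and Osgin1 1.46-fold, and Nqo1 and Me1 were 1.7-fold and 1.62-fold lower. Without KO replicate A, 4 rose and 11 fell. Fth1 and Txn1 were 1.21-fold and 1.19-fold lower (list median -0.09, camera adjusted p = 5.50e-05; adjusted p = 0.104 with an estimated correlation; 17 members adjusted over the list alone). Of 22 glycolysis genes 8 fell and 5 rose: Ldhb, Gapdh and Aldoa fell 1.42-fold, 1.2-fold and 1.16-fold, and Pfkp rose 1.16-fold. The list was called (median -0.11, camera adjusted p = 0.0249; adjusted p = 0.221 with an estimated correlation; 15 members adjusted over the list alone), and the call was lost without KO replicate A (camera adjusted p = 0.0828) and without WT replicate A (0.0541). Without KO replicate C or WT replicate B 2 of them rose, without WT replicate A or C 3 rose, and without WT replicate A 5 fell.

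Ligands and adhesion molecules that act on thymocytes rose more often than they fell, 14 and 2 of 29. Lgals3, Tgfb2, Wnt5a and Tnfsf10 were 2.46-fold, 1.63-fold, 1.60-fold and 1.46-fold higher (list median 0.17, camera adjusted p = 3.31e-05; adjusted p = 0.104 with an estimated correlation; 17 members adjusted over the list alone). Of 20 basement membrane and hemidesmosome genes 8 rose and 0 fell. Col17a1, a hemidesmosomal collagen, had 158 ± 9.53 CPM in KO and 84.2 ± 2.19 CPM in WT (n = 3 each), and Nid1, Lamb2 and Nid2 rose 1.49-fold, 1.42-fold and 1.27-fold (list median 0.08, camera adjusted p = 6.76e-06; adjusted p = 0.221 with an estimated correlation; 9 members adjusted over the list alone). Fibroblast and medullary TEC markers rose in the same libraries, with medians of 0.47 and 0.40.

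Markers of other thymic cells were higher in KO for some cell types; the labels do not describe the gate by which cTECs were isolated. Of 19 medullary TEC markers 8 rose and 0 fell: Cldn3 2.46-fold, Tnfrsf11a 1.78-fold, Krt14 1.32-fold and Krt5 1.30-fold, the last from 2481 ± 148 CPM to 3224 ± 57.2 CPM (n = 3 each). Aire, the regulator of tissue antigens, had 6.99 CPM in KO and 3.05 CPM in WT and was not called, nor was Ccl21a with 1367 and 1124 CPM. With the replicate block 11 rose, Aire and Ccl21a among them; without KO replicate C, 9 rose, Aire among them, and Trp63 fell. Aire was also called without WT replicate A. The list had a median of 0.40 (camera adjusted p = 1.18e-05; adjusted p = 0.104 with an estimated correlation; 10 members adjusted over the list alone). Of 14 thymic tuft cell markers 9 rose, among them Sh2d6 2.0-fold, Gng13 1.78-fold, the kinase Dclk1 1.7-fold and the regulator Pou2f3 1.45-fold (median 0.67, camera adjusted p = 1.33e-06; adjusted p = 0.234 with an estimated correlation; 12 members adjusted over the list alone). The tuft cell count was 5 without WT replicate A or C. Of 18 fibroblast and pericyte markers 11 rose and 1, Sfrp1, fell, with Thy1, Acta2, Col1a2 and Dcn 1.65-fold, 1.52-fold, 1.43-fold and 1.28-fold higher (median 0.47, camera adjusted p = 8.09e-07; adjusted p = 0.104 with an estimated correlation; 12 members adjusted over the list alone). Thy1 is also on the thymocyte list. With the replicate block 10 fibroblast and pericyte markers rose. Sfrp1 was not called there or without KO replicate B or C or WT replicate B or C, and 7 fibroblast markers rose without KO replicate B or WT replicate A. Of 19 dendritic cell and macrophage markers 9 rose, with Itgax, Lyz2, Cd14 and Mpeg1 3.40-fold, 2.42-fold, 2.02-fold and 1.41-fold higher (median 0.55, camera adjusted p = 3.62e-05; adjusted p = 0.124 with an estimated correlation; 10 members adjusted over the list alone). KO replicate A had the highest mean of the dendritic cell and macrophage markers (2.06 log2 CPM), of the thymocyte markers (2.64, against 1.64 to 1.86 in the other libraries) and of the endothelial markers (2.03). It was also highest for the tuft cell markers (3.31, against 2.76 and 2.82 in KO replicates B and C), the medullary TEC markers (4.54) and the B cell markers (2.21). Without KO replicate A, 7 medullary TEC, 7 tuft cell, 11 fibroblast and 6 dendritic cell and macrophage markers were called higher, and 14 cortical TEC markers were called lower. The tuft cell median was then 0.51. All counts of called list members without a library or with the block were chosen after the data were seen.

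**Figure D3:**
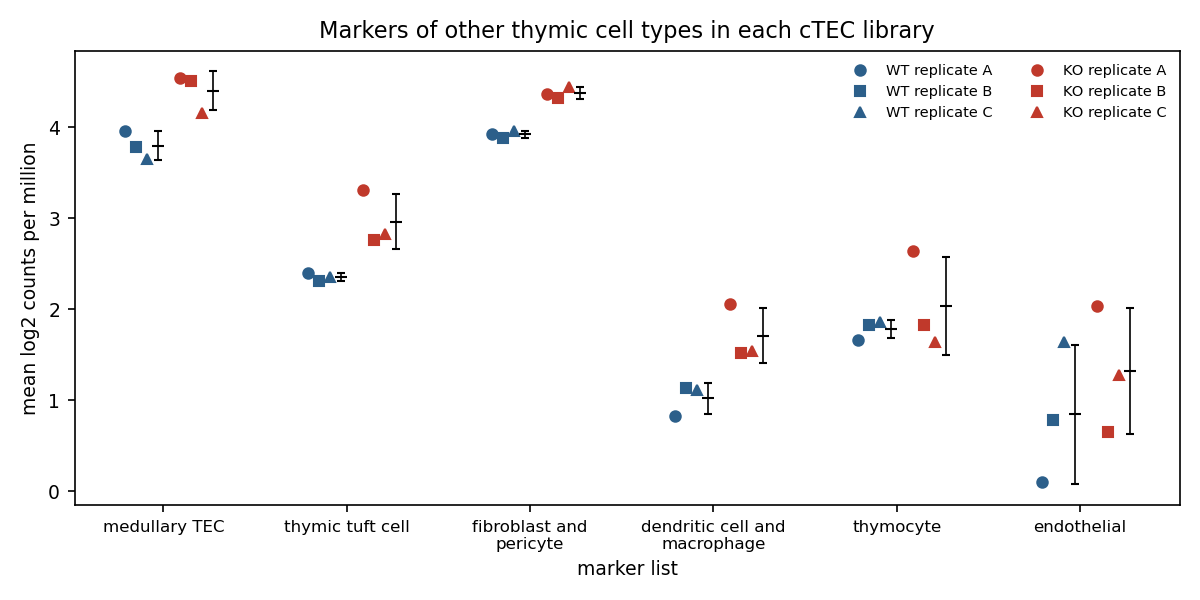
Mean log2 CPM of the markers of 6 other thymic cell types in each library, with the mean and SD of each genotype in black. The thymocyte mean is 2.64 in KO replicate A and 1.64 to 1.86 in the other libraries.

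Several lists were not called. Of 24 thymocyte markers 2, Thy1 and Cd28, rose (1.65-fold and 1.55-fold; camera adjusted p = 0.160, 2 members adjusted over the list alone), with a median log2 fold change of 0.18. Without KO replicate A that median was -0.11 (camera adjusted p = 0.762), and without KO replicate C the list was called, with a median of 0.36 (camera adjusted p = 0.00199). Cd28 was not called with limma on TPM, and Thy1 is also on the fibroblast and pericyte list. None of 16 endothelial markers was called, with Pecam1 at 9.57 CPM in KO and 6.28 CPM in WT and Vwf at 7.27 and 4.12 CPM (median 0.48, camera adjusted p = 0.377, 0 adjusted over the list alone). Without KO replicate A the median was -0.01 (camera adjusted p = 0.934) and Cldn5 was called lower, and without WT replicate C the list was called with a median of 1.03 (camera adjusted p = 0.0242) and 1 marker rose. None of 5 B cell markers was called, with Ebf1 at 19.1 and 19.3 CPM (camera adjusted p = 0.525, 0 adjusted over the list alone), and 1 rose without KO replicate B or C or WT replicate C. Of 5 measured tissue-restricted antigens Crp rose 2.69-fold and Afp fell 7.46-fold, both below 1 CPM in each group (camera adjusted p = 0.391, 4 adjusted over the list alone), and Afp was not called with DESeq2. Of the antigens 2 rose without KO replicate B or WT replicate A or C, or with the block. Lysosomal genes moved both ways: of 22, the cathepsins Ctsh, Ctsc and Ctsz rose 2.22-fold, 1.52-fold and 1.40-fold and 4 genes fell, Atp6v0d1 1.13-fold among them (camera adjusted p = 0.305, 7 adjusted over the list alone), and without WT replicate C 1 fell. Of 24 autophagy genes 5 fell and 1 rose, with Optn and Gabarapl1 1.35-fold and 1.23-fold lower (camera adjusted p = 0.0982, 6 adjusted over the list alone). Without KO replicate A or WT replicate B or C 3 of them fell, and the rise, Rb1cc1, was called only with all libraries, with the block or without KO replicate A. Of 21 genes of the unfolded protein response 3 rose and 1 fell, with Ppp1r15a and Dnajb9 1.29-fold and 1.24-fold higher and Asns 1.21-fold lower (camera adjusted p = 0.504, 4 adjusted over the list alone), and 3 fell without KO replicate C and 2 without WT replicate C or with the block. Of 22 heat shock genes 5 rose and 2 fell, with Dnaja1 1.31-fold higher (camera adjusted p = 0.377, 9 adjusted over the list alone), and without WT replicate A the list was called (camera adjusted p = 0.0492), with 5 rises and 0 falls. The rises and falls were 2 and 1 without KO replicate A, 5 and 0 without KO replicate B, 3 and 4 without KO replicate C, and 3 and 1 without WT replicate B or C. Of 30 cell cycle genes 3 fell, with Mcm2 1.19-fold lower (camera adjusted p = 0.525, 1 adjusted over the list alone). Mcm4 and Mcm6 were not called without KO replicate A or C or any WT replicate: 1 gene fell without KO replicate A or C or WT replicate B or C, and Top2a rose without WT replicate C. With the block 2 fell. With all libraries, neither gene was called with DESeq2, upper quartile normalization, a mean of at least 5 CPM, RSEM counts, limma on TPM, the thymocyte covariate or the test against a fold change of 1.2. Of 10 mitochondrially encoded genes mt-Nd2 rose 1.14-fold (camera adjusted p = 0.525, 0 adjusted over the list alone), and its call was lost without KO replicate A, KO replicate B or any 1 of the WT replicates and with limma on TPM, while 3 rose without KO replicate C.

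**Figure D4:**
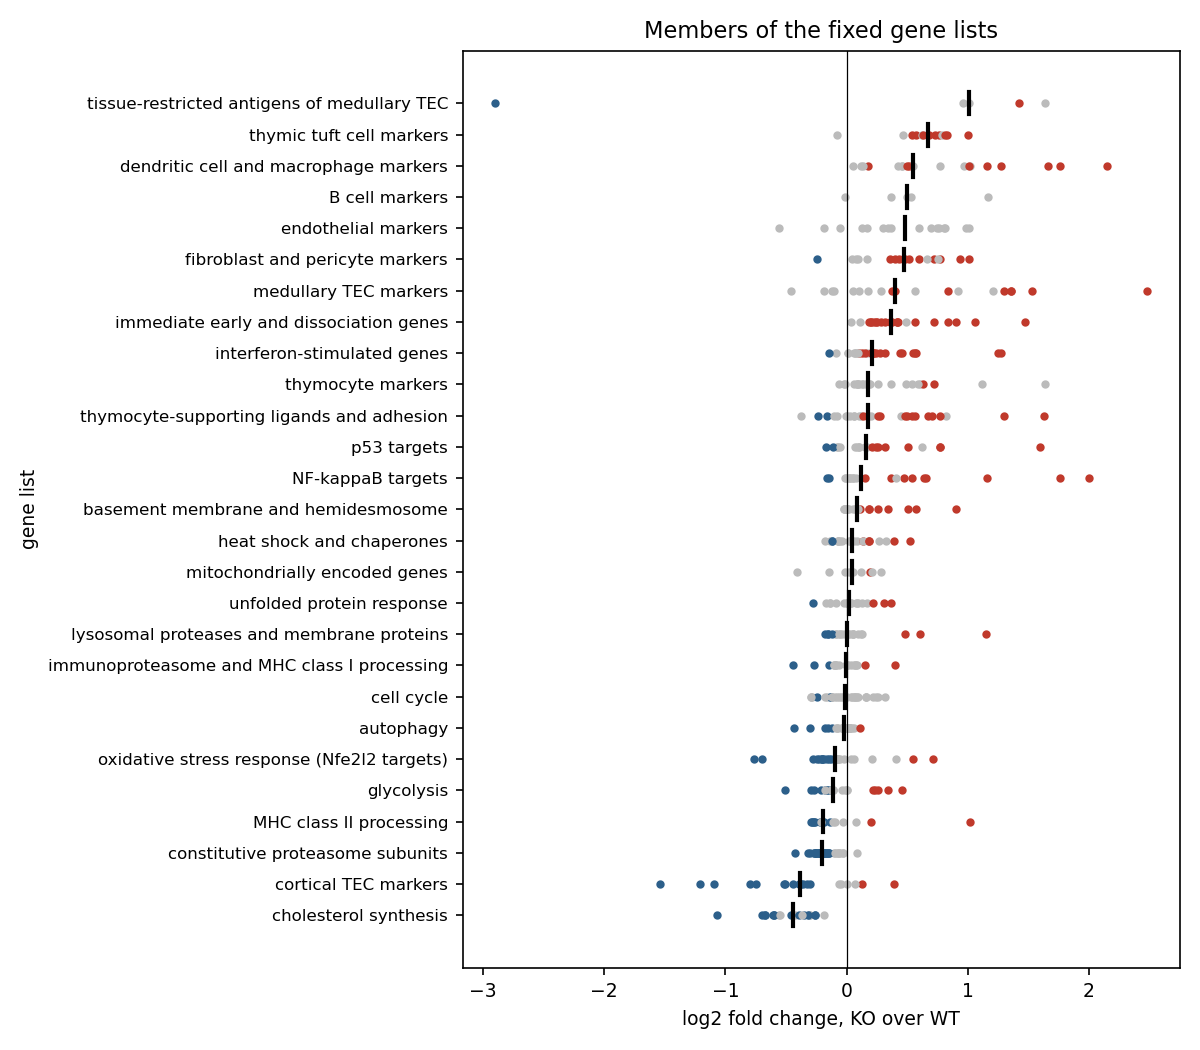
Log2 fold change (KO over WT) of the measured members of 27 gene lists, 1 point per gene, coloured where called (red higher, blue lower in KO) and grey where not, with each list's median as a black bar. The medians run from -0.44 for cholesterol synthesis to 1.01 for the tissue-restricted antigens.

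More genes were detected in the KO libraries, in which markers of medullary TECs, tuft cells, fibroblasts and dendritic cells and macrophages were also higher. Whether the added genes come from cTECs was not tested. At 1 CPM or more there were 14236, 14095 and 14038 genes in KO replicates A, B and C and 13776, 13772 and 13861 in WT replicates A, B and C. The means were 14123 ± 102 and 13803 ± 50.3 genes, a difference of 320 (n = 3 each, exact two-sided permutation p = 0.1). With 20 regroupings, 0.1 is the smallest p that this design can give.

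Genes near Psmb11 were called about as often as genes elsewhere. Within 10 Mb, 44 of 194 genes were called (22.68%), against 23.56% of other genes (odds ratio 0.952, 95% interval 0.663 to 1.34, Fisher's exact p = 0.865). Among them Lgals3 and Samd4 were 2.46-fold and 1.51-fold higher (Samd4 was not called with limma on TPM), Phf11d had 80.6 CPM in KO and 64.5 CPM in WT, and Dhrs1 was 1.27-fold lower. The Y-linked gene Uty had 16.2 to 19.7 CPM in the 6 libraries. Xist had 138 CPM in WT replicate A and 243 to 251 CPM in the other libraries. Transcripts of Xist and of Y-linked genes were thus found together in every library, and the labels state neither the sex of the mice nor whether mice were pooled.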

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

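The tests of splits, of other cell types and of the segment around the Ifi200 genes were chosen after the results were seen. That of the segment around Psmb11 was chosen before. The test of shared reads concerned genes noticed in the results, so it was chosen before its own result only.

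The share of reads assigned to no gene, which no comparison used, averaged 10.4% ± 0.525 in KO and 9.65% ± 0.163 in WT (n = 3 each), with every KO library above the highest WT library (9.92% against 9.83%). The exact two-sided permutation p was 0.1, the smallest possible.

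The genotypes gave 3989 called genes, and the highest of the other 9 splits of the 6 libraries gave 1. With 10 splits no share under 0.05 can be reached, and 1 split, the real one, gave as many. Each other split mixes the genotypes, which puts their difference into the spread within groups. Few calls there are therefore not separate support. The calls were not concentrated in a segment around Psmb11, since 44 of them lay within 10 Mb and the odds ratio there was 0.952. That comparison cannot see an effect of a segment carried along with the allele on genes elsewhere. The genotype stays open as the biological explanation and was not tested apart from cell isolation and the handling of the mice.

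Lower cortical TEC markers came with higher markers of other cells. Thymocytes, dendritic cells, macrophages, B cells and endothelial cells are unlikely as the whole source: their 64 markers together gained 102 CPM, while 20 cortical TEC markers lost 4160 CPM, a comparison that takes both sets of markers to be about as abundant in their own cells. Axl, the most abundant of the 64, had 272 CPM in KO and 263 CPM in WT and was not called, and Lyz2 had 24.8 and 10.2 CPM. A larger share of medullary epithelium or fibroblasts in the KO libraries may account for part of the fall and cannot be told apart from a change within cTECs. The cortical markers fell unequally (heterogeneity Q = 612.7 over 19 degrees of freedom), but which of them the other cells also express is not known from these libraries.

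The interferon-inducible Ifi200 genes on chromosome 1 (173350879 to 174031810) were called higher together, 12 of 12 tested with a median log2 fold change of 1.198, among them Mndal (38.1 and 19.1 CPM in KO and WT), Ifi203 (37.0 and 18.2), Ifi202b (37.9 and 18.7) and Ifi204 (41.6 and 26.0). Members were taken by name, with Mndal and Aim2, and other genes inside the span were left out. Some had few counts, such as Ifi208 and Ifi209 with 0.268 and 0.340 CPM in WT. Ifi211 lies within the span of Mndal, and Ifi203 overlaps Mndal over nearly all its length. The members are therefore not all independent, Mndal and Ifi203 among them. The Ifi200 genes were noticed in a scan of 238 segments of 10 Mb, where that from 170 to 180 Mb held the strongest excess of calls of 1.5-fold or more (22 of 101 genes, Fisher's exact p adjusted over the segments = 1.40e-04). Reads shared between these related genes are an unlikely source, since RSEM counts, which divide shared reads, gave a median of 1.07. A strain segment around the genes may contribute and cannot be told apart from the genotype: 10 of 89 neighbours within 5 Mb were called at 1.5-fold or more, against 6.53% of other genes (odds ratio 1.81, 95% interval 0.834 to 3.52, Fisher's exact p = 0.0830). RNA from dendritic cells and macrophages, whose markers rose in the same libraries (median log2 fold change 0.55, 9 of 19 called), and an effect of the missing subunit stay open.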

How the results depend on the processing

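The test against a fold change of 1.2, leaving out libraries for the genes detected, the genes near Psmb11 and the called members of lists, and the block for the last 2 were chosen after the data were seen. Psmb11 stayed called in all alternatives, with log2 fold changes from -6.21 to -7.86. The count of 3989 genes moved by more than 1.5 times with limma on log2(TPM + 1), to 2033 (1221 higher, 812 lower), on log2(TPM + 0.1), to 1993 (1194 and 799), and with the test against a fold change of 1.2, to 954 (752 and 202), where small changes are excluded by construction; the cause was not tested for limma. The other alternatives with all libraries gave 3181 to 4487 genes, and DESeq2 called 3416 of the 3989 in the same direction. Leaving out a library gave 2715 to 3661 genes (1476 to 1917 higher, 1239 to 1744 lower, the lowest without WT replicate C), with fewer samples in each fit. The replicate letters did not pair the libraries (correlations of deviations -0.016, 0.082 and -0.034), and with the letter as a block 4097 genes were called. The 16 called lists became 0 with an estimated correlation and 15 to 17 without a library. With an estimated correlation camera uses the residual degrees of freedom of the libraries. With a preset one it uses a far larger number, set by the genes tested. That difference raises p by itself, and lists with an estimated correlation near the preset 0.01 lost their call too. How much of each loss it accounts for was not tested. For the thymocyte-supporting ligands the estimate (-0.026) was below the preset, yet the unadjusted camera p rose from 1.23e-05 to 0.00777. Correlation between members was thus not the source for that list. A call lost with an estimated correlation is not by itself a sign that members vary together. A separate test, fry, asks whether members changed at all and not whether they changed more than other genes, so its 19 lists, or 23 in either direction, are not the same count. Genes detected differed by 156.7 to 396.3 at other thresholds and by 263.5 to 362.5 without a library, each with exact permutation p = 0.1. The odds ratio near Psmb11 lay between 0.851 and 1.09. Of 117 called named genes 74 kept call and direction in all 18 settings, 43 lost the call in at least 1 and 0 reversed; 37 lost it in the test against a fold change of 1.2. What depth limits was not tested by thinning for single genes; genes with few counts had wide errors, such as Afp with an SE of 0.52 on the log2 scale.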

Other observations

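The gene lists of this part, and their tests, were all chosen after the largest changes had been seen, so their direction is not independent evidence.

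Genes of specialised epithelia were higher in KO cTEC libraries, in which the markers of medullary TECs, tuft cells and fibroblasts were also higher, with median log2 fold changes of 0.40, 0.67 and 0.47. Whether the cells that carry these transcripts are cTECs was not tested. Of 18 measured mucosal and secretory genes 13 rose and 0 fell, with a median log2 fold change of 1.12 (camera adjusted p = 5.38e-19; adjusted p = 0.0893 with an estimated correlation). The mucin Muc16 had 12.7 CPM in KO and 4.43 CPM in WT, and the transcription factor Ehf was 1.99-fold higher. Bpifa1, the most abundant of the list, had 746 and 344 CPM and was not called (edgeR adjusted p = 0.164). Of 8 microfold cell markers 7 rose, among them the receptor Gp2 (94.4 and 44.2 CPM) and the regulator Spib (19.86 CPM in KO, 1.80-fold higher), with a median of 1.04 (camera adjusted p = 1.80e-06; adjusted p = 0.135 with an estimated correlation). Of 10 keratinocyte differentiation genes 6 rose, among them Krtdap (24.3 and 11.2 CPM) and Dsg1a (9.07 and 4.06 CPM), with a median of 0.88 (camera adjusted p = 5.82e-06; adjusted p = 0.0893 with an estimated correlation). The microfold and keratinocyte lists share 2 and 3 genes with the lists fixed beforehand, and the enterocyte and hepatocyte list below shares 3. Muc4, Muc20, Sftpd and Spink5 had been seen among the called genes, as had Ttn of the muscle list and Nefm of the neuroendocrine list.

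Of 13 ciliated cell markers 4 rose, among them the regulator Foxj1 (7.68 and 3.66 CPM), and Dnah9 fell (camera adjusted p = 0.00309; adjusted p = 0.138 with an estimated correlation). Of 6 skeletal muscle genes Ttn, Neb and Des rose (camera adjusted p = 0.00309; adjusted p = 0.135 with an estimated correlation). Of 11 enterocyte and hepatocyte genes 4 rose, Krt20, Lypd8, Cdx1 and Cdhr5 (camera adjusted p = 0.00309; adjusted p = 0.179 with an estimated correlation). Of 10 neuroendocrine genes 3 rose and 2, Nefm and Scg2, fell, and the list was not called (camera adjusted p = 0.637).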
